A study of Mus musculus with 23 samples.

How the data were processed

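The series measured messenger RNA by sequencing in 23 libraries of mouse oligodendrocyte lineage cells in 8 groups. Oligodendrocyte progenitor cells (OPCs) had been made from the epiblast stem cell lines EpiSC5 and 129O1, of mouse strains 129SvEv and 129S1/SvImJ, per the labels; the same protocol text, on every label, ties EpiSC5 to replicate 1 and 129O1 to replicate 2 of OPCs, while the labels of all SOX6 experiment libraries list tables named for EpiSC5, so the line of each library was left open and not used. Sorted OPCs and sorted oligodendrocytes (OLs) had 3 libraries each. The SOX6 experiment had 17 libraries. OPCs carried a non-targeting guide (3 libraries), SOX6 guide 1 (2 libraries) or SOX6 guide 2 (3 libraries), and cells moved to a medium that permits differentiation had 3 libraries for each guide. Per the labels' protocols, the guides came from a lentiviral CRISPR library vector, cells were selected with puromycin at 500 ng/mL for 96 hours, and the cells were then kept for 60 hours in growth or differentiation medium. The label word OL is used here for all cells kept in differentiation medium; the culture was not sorted for them.

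Per the submitters' processing notes, transcripts were quantified with Salmon 0.14.1, DESeq2 was used and the build was mm10; the version of DESeq2 is not given in the sources used here. The authors deposited estimated counts per gene symbol for the SOX6 experiment, in 1 table for OPCs and 1 for OLs, and these are not whole numbers. The authors deposited TPM (a measure that scales each library's transcripts to one total) for all libraries, and for the sorted cells TPM alone was used here. The authors also deposited tables of log2 fold changes (control over targeted) with adjusted p-values. The TPM of a library summed to between 77.6% and 79.6% of the full TPM scale over the deposited symbols. The sorted table has 26 names that are dates in place of gene symbols, and these could match no gene. The library kit named in the labels selects poly(A) RNA and does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart, and close copies of a gene can share reads.

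Estimated counts were rounded to whole numbers. Genes were kept with filterByExpr (minimum count 10, minimum total 15) and libraries were scaled by TMM. Tests were the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each stage was fitted alone with 1 coefficient per group. The main contrast was the mean of both guides minus control. Each guide against control, guide 2 minus guide 1, and the response of OLs minus that of OPCs (both stages in 1 fit) were further contrasts. Control OLs were compared with control OPCs across both tables. The sorted cells were tested with limma 3.58.1 on log2(TPM + 1) for genes with a TPM of at least 1 in at least 3 of the 6 libraries. The depth behind the TPM values is unknown. Fold changes of the sorted cells are on the log2(TPM + 1) scale, which understates the change of genes with low values. CPM are counts scaled to a common library total after TMM.

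In all, 19 gene lists with 318 entries were fixed. They cover myelin and mature oligodendrocyte, newly formed oligodendrocyte, oligodendrocyte progenitor, differentiation transcription factor, progenitor or inhibitory transcription factor, cholesterol synthesis, fatty acid and sphingolipid synthesis, cell cycle, interferon response, p53 response, and unfolded protein and integrated stress response genes. Further lists hold markers of astrocytes, neurons, microglia, fibroblasts or pericytes, Schwann cells, pluripotent cells, slow muscle and cartilage. Each list was tested with fry and with camera (limma), the latter with a preset correlation of 0.01 and with an estimated one, and adjusted over the lists. The p of fry tests whether a list's genes moved, on balance, one way; it does not compare the list with other genes. Genes at least 4-fold higher in sorted OLs (647) or in sorted OPCs (592) were tested the same way in the SOX6 experiment. The groups, tests, gene lists, rule for named genes and most alternative settings were chosen before the data were examined.

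Named genes were, for each main comparison, the 10 with the largest rise and the 10 with the largest fall among genes past the threshold, with a mean of at least 10 CPM or TPM in the higher group and with every targeted library beyond all control libraries (for the sorted cells, every library of 1 group beyond all of the other). Predicted genes, mitochondrial genes and ribosomal protein genes were left out by that rule. For the difference between stages the 5 largest in each direction were taken, without the condition on libraries. Members of a list could be named as its examples. Sox6 was always named. A few single-gene results that the rule or a list would allow are not reported here, and such genes stay in the counts and lists.

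Gene positions came from GENCODE M21 on GRCm38 (mm10). Of 35385 symbols in the count tables, 34810 (98.38%) matched 1 gene model. The guide sequences were matched to the transcripts of that release, and sites without an exact match in a transcript were not searched. Libraries of a group were compared in pairs by the chi-square per degree of freedom of their counts, which ran from 5.70 to 103.3, so no pair lay within sampling noise and none was merged. The count tables mark libraries of a group with letters, which were used as names only.

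Total counts ran from 13967438 to 16958611 in the OPC libraries and from 13124580 to 18551822 in the OL libraries. A count of 0 allows up to 3 counts, which is 0.162 to 0.229 CPM; this limit covers counting error only. The pipeline was tested on simulated counts drawn from the real means. In 13110 simulated OPC genes, edgeR recovered 49.3% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 77.3% of those changed 4-fold, with 5 false among 132 calls. In 13205 simulated OL genes it recovered 16.4%, 55.2% and 77.3%, with 8 false among 107. For the difference between stages in 14013 genes it recovered 20.9%, 46.3% and 65.2%, with 4 false among 92. DESeq2 had 40 false among 180, 44 among 164 and 25 among 129 calls in these simulations. The counts were drawn with the spread per gene that edgeR had estimated, which may favour edgeR. In 11902 simulated genes of the sorted cells limma recovered 5.97%, 67.2% and 92.4%, with 2 false among 112.

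Alternatives were relative log expression size factors, library totals, no filter beyond 1 count, a stricter filter at a mean CPM of 1, DESeq2 1.42.0, both guides pooled, both stages in 1 fit, genes at least 2-fold higher in sorted cells in place of 4-fold, each library left out in turn, and, for the sorted cells, a pseudocount of 0.1, other TPM filters and median centring. Alternatives added after the data were seen were a transcript length offset per gene and library (from the ratio of estimated count to TPM), removal of each library's loess trend on transcript length, and leaving out a pair of OL libraries that stood apart. Because both guides share the control libraries, 20 simulations per stage drew all groups, controls included, from equal means. They gave the overlap and correlation that arise with no effect and with the spread of each gene alone. Figures were drawn with matplotlib 3.10.9.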

Results

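Poly(A) RNA was sequenced from mouse oligodendrocyte progenitor cells (OPCs) grown from epiblast stem cells and from oligodendrocytes (OLs) made from them. The series title places the work around gene control of when oligodendrocytes mature. One set compared OPCs with O1-positive OLs, each purified on magnetic beads (3 libraries each, as TPM). The other set, with 17 libraries, followed cells after CRISPR targeting of Sox6, which encodes a transcription factor of the SOX family. It held 8 libraries of cells in OPC growth medium and 9 libraries of cells kept for 60 hours in a medium that permits differentiation but has no thyroid hormone, called OLs below. Total counts ran from 13967438 to 16958611 in the OPC libraries and from 13124580 to 18551822 in the OL libraries. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Errors are standard deviations (SD) for levels and standard errors (SE) for log2 changes.

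Sox6 RNA was lower in every targeted library than in every control library of its stage. In OPCs it stood at 200 ± 34.2 CPM with the non-targeting guide (SD, n = 3), 81.9 ± 9.87 CPM with guide 1 (n = 2) and 76.1 ± 9.57 CPM with guide 2 (n = 3). The 3 control OPC libraries read 165.4, 200.8 and 233.7 CPM, those with guide 1 read 88.9 and 74.95 CPM, and those with guide 2 read 74.4, 67.4 and 86.4 CPM. In OLs it stood at 413.8 ± 25.1 CPM in controls, 219.2 ± 54.3 CPM with guide 1 and 254.2 ± 1.34 CPM with guide 2 (n = 3 each). The control OL libraries read 416.6, 437.3 and 387.4 CPM, those with guide 1 read 258.6, 157.2 and 241.7 CPM, and those with guide 2 read 254.7, 252.7 and 255.3 CPM. The level with guide 1 and guide 2 was 40.98% and 38.04% of control in OPCs, and 52.98% and 61.4% in OLs.

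By edgeR, Sox6 changed by -1.32 (SE 0.127, adjusted p = 0.00147) in OPCs and by -0.81 (SE 0.14, adjusted p = 0.0095) in OLs, as log2 over both guides. The call in OLs was lost without control library A (-0.80, adjusted p = 0.0591), without control library B (-0.77, adjusted p = 0.0636) and with a transcript length offset (-0.86, adjusted p = 0.105). With single guides the changes were -1.25 and -1.39 in OPCs (adjusted p = 0.00935 and 0.00314) and -0.91 and -0.71 in OLs (adjusted p = 0.0161 and 0.04996). The guide 1 call in OPCs was lost without either of its own libraries (adjusted p = 0.0927 without A and 0.125 without B) and with the length offset (0.0891). In OLs the guide 1 call was lost without control library A, B or C (0.0754, 0.0796 and 0.0601) and with the length offset (0.084). The guide 2 call in OLs lay at the threshold and was lost with RLE size factors (0.0513), with library totals (0.0599), with the length offset (0.482), without control A, B or C (0.177, 0.187 and 0.132), without guide 1 library C (0.0594) and without guide 2 library A, B or C (0.161, 0.148 and 0.153). In the authors' deposited table the log2 of control over targeted Sox6 was 1.49 in OPCs (adjusted p = 3.01e-05) and 0.83 in OLs (adjusted p = 0.0593).

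Sox6 lies on the minus strand of chromosome 7 from 115470872 to 116038796 (GRCm38, GENCODE M21). Guide 1 (TTGACGGAATGAACTGTACG) matched positions 115580612 to 115580631, in the coding part of exon 9 of the 17 exons of transcript ENSMUST00000072804.10, on the strand opposite to the transcript and beside a GGG motif. Guide 2 (AGAACACGCTTTGAGAACCT) matched positions 115512747 to 115512766, in the coding part of exon 14 of that transcript, on its own strand and also beside GGG. The non-targeting guide had 0 exact matches among the annotated transcripts. A guide changes DNA and need not lower RNA, so the RNA level is only a partial check of targeting; the edits themselves were not analysed here.

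**Figure D1:**
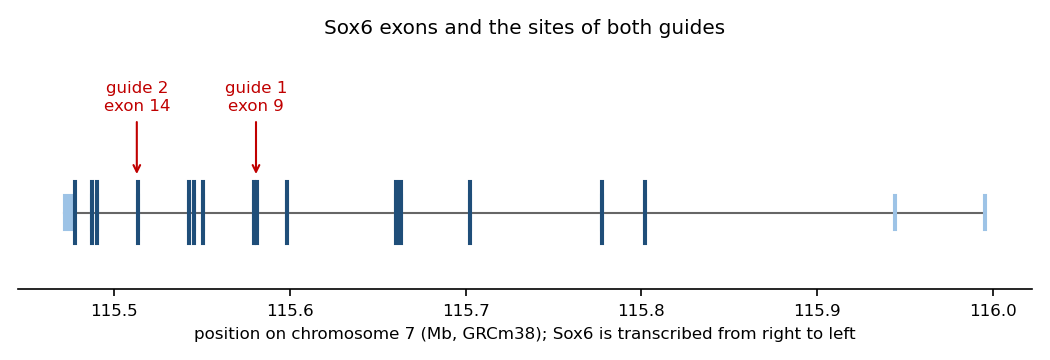
Exons of Sox6 transcript ENSMUST00000072804.10 along chromosome 7 (GRCm38 position), with the sites of both guides. Guide 1 lies in exon 9 and guide 2 in exon 14 of 17.

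**Figure D2:**
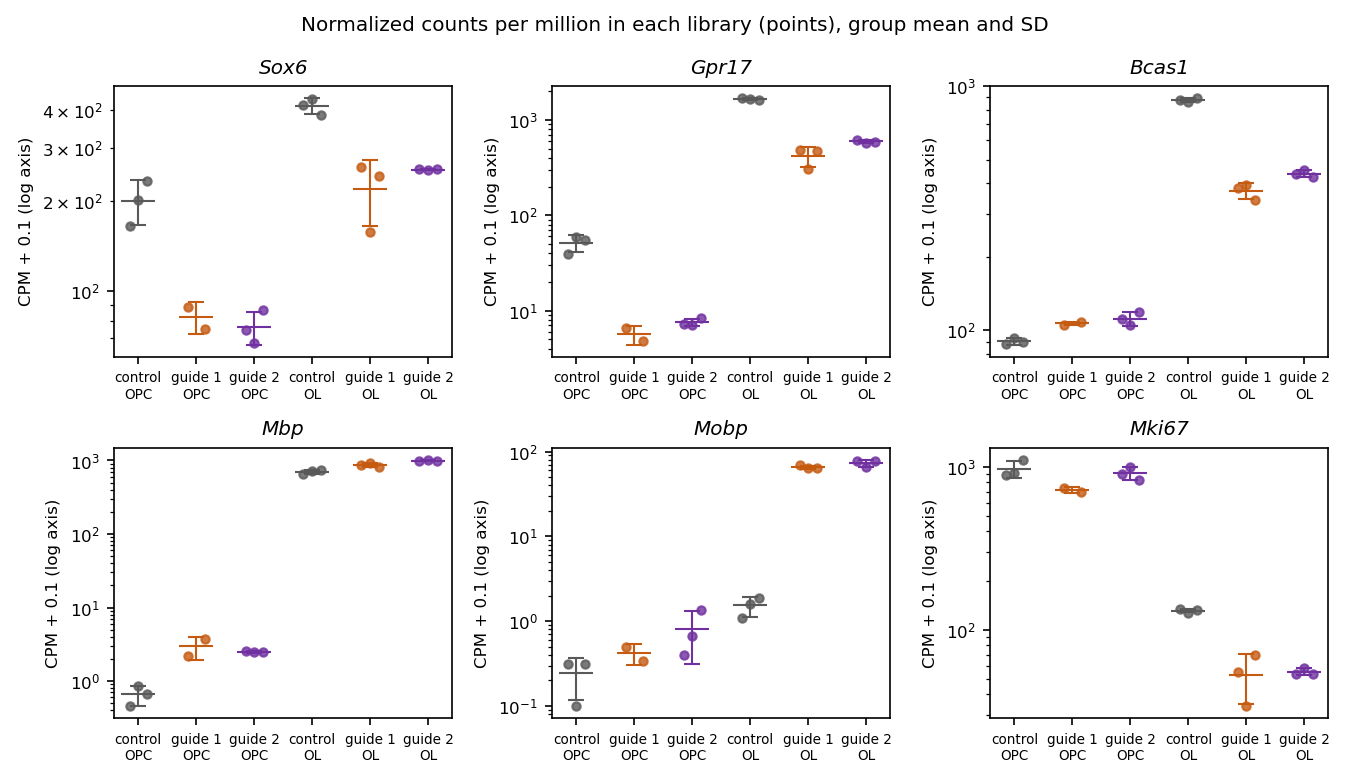
Level of 6 genes in each of the 17 SOX6 experiment libraries as CPM + 0.1 on a log axis, 1 point per library, with the group mean and SD as bars. Sox6 and Gpr17 sat lower in every targeted library than in all control libraries of the same stage.

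The comparison of sorted OLs with sorted OPCs gives the reference for differentiation. Myelin genes led the rise. Mbp, which encodes myelin basic protein, went from 0.282 ± 0.214 to 16290 ± 325 TPM (SD, n = 3 each). Mag, a myelin adhesion molecule, was listed at 0 in the sorted OPCs and stood at 1568 ± 97.6 TPM in the sorted OLs. The largest falls included genes of dividing cells, such as Pimreg (214.3 ± 21.4 to 2.79 ± 1.89 TPM), the topoisomerase Top2a (317.0 ± 21.3 to 8.45 ± 3.81 TPM) and cyclin D1, Ccnd1 (131.6 ± 31 to 2.18 ± 0.393 TPM), and the matrix gene Tnc, for tenascin C (124.7 ± 10.6 to 1.49 ± 0.563 TPM). Sox6 itself rose from 61.5 ± 13.3 to 105.7 ± 17.3 TPM (log2 0.78, SE 0.195, adjusted p = 0.014).

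Other genes with the largest rises were Tmem163, Mobp, Tubb4a, Tnr, Rasgef1b, Kcna1 and Dusp15, with log2 changes from 7.35 to 8.18. Other large falls were in Fbln2, Etv4, Kif23, Chst7, Rassf3 and Pbk, with log2 changes from -5.43 to -5.16. Their adjusted p by limma ran from 1.96e-07 to 4.39e-05 over all 20 named genes. In all, 7160 of 11902 genes passed the test, 3132 higher and 4028 lower, of which 1669 and 1989 changed at least 2-fold. The median gene changed by -0.136 on the log2 scale, and with median-centred libraries 3484 were higher and 3570 lower.

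Of 19 measured myelin genes, 17 rose and 1 fell with a median log2 change of 4.26; for every list of this comparison named here, the counts adjusted over the list alone were the same. All 15 measured genes of newly formed oligodendrocytes rose, among them the receptor Gpr17 (11.5 to 847.5 TPM) and Bcas1 (34.7 to 2846 TPM), with a median of 3.85. The fry test gave adjusted p = 1.04e-06 for the first list and 2.16e-06 for the second, and camera gave adjusted p = 0.0907 for each with an estimated correlation. Of 27 cell cycle genes 26 fell, with a median of -4.26 (fry adjusted p = 7.83e-05, camera adjusted p = 0.396 with an estimated correlation). Of 20 progenitor genes 5 rose and 14 fell, with a median of -1.21 (fry adjusted p = 0.0185, camera adjusted p = 0.468 with an estimated correlation). Of 24 cholesterol synthesis genes 13 rose and 3 fell, with a median of 0.40 (fry adjusted p = 0.00146, camera adjusted p = 0.45 with an estimated correlation). Astrocyte markers summed to 656.2 ± 37.6 TPM in sorted OPCs and 2163 ± 1010 TPM in sorted OLs. Of 14 measured ones 5 rose and 5 fell, and the list had no call (fry adjusted p = 0.519, camera adjusted p = 0.83 with an estimated correlation). These values do not decide whether the sorted groups differ in astrocyte RNA as such.

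A related step, from growth medium to a medium that permits differentiation, was measured in the control cells of the SOX6 experiment. The OLs here were an unsorted culture kept without thyroid hormone, whereas the sorted OLs had been purified. The end points of these comparisons were therefore not matched. Mbp went from 0.558 to 704.9 CPM and Gpr17 from 51.3 ± 10.4 to 1641 ± 42.7 CPM (SD, n = 3 each). The sialidase gene Neu4 went from 1.05 ± 0.467 to 78.2 ± 4.08 CPM. The mitotic kinase gene Cdk1 went from 181.3 to 19.8 CPM. Of 20 measured myelin genes, 12 rose and 1 fell (the same over the list alone; median log2 2.4), and of 16 newly formed oligodendrocyte genes 8 rose and 2 fell (list alone, 9 and 2; median 2.29). Of 30 cell cycle genes 27 fell and none rose (list alone, 28; median -2.63). These 3 lists kept an adjusted p of 0.000302 by camera with an estimated correlation. The progenitor list went mostly up here, with 12 of 21 genes higher and 5 lower (the same over the list alone; median 0.43, camera adjusted p = 0.00485 with an estimated correlation), among them Pcdh15 (log2 3.07) and Tnr (log2 5.14), while Cspg4, which encodes the NG2 proteoglycan, went from 300.5 to 185 CPM.

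The edgeR test called 6178 of 14352 genes between control OLs and control OPCs, 3074 higher and 3104 lower. Across 11655 genes tested in both, the change in control cells and that in sorted cells had a Pearson r of 0.637, where genes are not independent replicates. Shared calls were 1453 higher and 2067 lower, against 688 and 1000 for independent lists, and 514 genes were called in opposite directions. Markers of astrocytes also moved with stage: their summed level was 1678 ± 81.7 CPM in control OPCs and 7095 ± 197 CPM in control OLs, and Apoe went from 54.2 to 2175 CPM. The neuron list stood at 1474 ± 156 and 2547 ± 57.5 CPM. The 2 stages came as separate tables, so a batch between tables cannot be told apart from stage.

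The first SOX6 comparison asks what targeting changes in progenitors. In targeted OPCs the largest fall was in Gpr17, a receptor of committed oligodendrocyte precursors. It stood at 51.3 ± 10.4 CPM in controls (n = 3), 5.58 ± 1.26 CPM with guide 1 (n = 2) and 7.46 ± 0.638 CPM with guide 2 (n = 3), which is 7.82-fold lower. The Notch ligand gene Dll3 went from 43.3 ± 0.56 to 18.6 ± 1.28 and 16.6 ± 0.768 CPM with guide 1 and guide 2. The kainate receptor gene Grik3 went from 74.0 ± 12.5 to 26.8 ± 1.79 and 31.5 ± 2.2 CPM. Lpo, which encodes lactoperoxidase, rose from 36.6 ± 2.31 to 79.5 ± 3.94 and 85.3 ± 1.19 CPM.

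The log2 changes over both guides, by edgeR, were -2.97 for Gpr17 (SE 0.162, adjusted p = 0.000139), -1.28 for Dll3 (SE 0.0666, adjusted p = 0.000127), -1.33 for Grik3 (adjusted p = 0.00074) and 1.19 for Lpo (SE 0.0593, adjusted p = 0.000127). Further falls were in Pstpip2 (-1.71), C1ql1 (-1.67), Pcdh15 (-1.52), Ppfibp1 (-1.32), Lrp1 (-1.26) and Dop1a (-1.21). Further rises were in Acad11 (2.86), Ntm (1.33), Car8 (1.304), Dll4 (1.17), Fbxo32 (1.02), Dsc1 (0.98), the metalloprotease gene Adamts4 (0.98) and Gpr37 (0.96). Their adjusted p ran from 0.000737 to 0.0467. Acad11 was uneven, at 0.61 CPM in controls, 1.95 ± 0.647 CPM with guide 1 and 10.1 ± 8.37 CPM with guide 2. Of the 19 genes the rule took, 12 kept their call in every alternative. The call of Dsc1 was lost without any 1 of the 8 libraries (adjusted p from 0.0553 to 0.139). That of Dop1a was lost without any but control library C (0.0568 to 0.155), and that of Acad11 without any but guide 2 library A or B (0.0767 to 0.15). Fbxo32 lost its call without control B (0.0579) or guide 1 library A (0.0617). With a length offset the calls of Pcdh15 (0.14), Ppfibp1 (0.0843), Dsc1 (0.0939), Acad11 (log2 1.85, adjusted p = 0.391) and Dop1a (log2 -0.44, adjusted p = 0.282) were lost.

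Of 21 measured progenitor genes, 7 fell and none rose in targeted OPCs (10 fell and 1 rose when adjusted over the list alone). They include C1ql1, Pcdh15, Tnr (25.3 to 11.9 and 12.7 CPM) and Lhfpl3 (101.8 to 56.3 and 55.2 CPM). Not all of these mark progenitors alone. C1ql1 and Pcdh15 went from 14.3 to 91.7 and from 10.7 to 90.3 CPM from control OPCs to control OLs. Tnr went from 2.05 to 613.4 TPM from sorted OPCs to sorted OLs, while Pcdh15 fell there (3.47 to 0.99 TPM) and Lhfpl3 had no call. The fall of this list therefore cannot be read as a loss of progenitor genes alone. The list had a median log2 change of -0.20, with fry adjusted p = 0.00755 and camera adjusted p = 0.0542 with an estimated correlation. Of 14 myelin genes 4 rose and 1 fell, the same counts as over the list alone. Those that rose included Mbp (0.558 to 2.86 and 2.39 CPM), Cnp (139.3 to 209.4 and 194.3 CPM) and Car2 (log2 0.34), and Gsn fell by 0.83 on the log2 scale. That list had a median of 0.18 (fry adjusted p = 0.104). Of 13 newly formed oligodendrocyte genes, Bcas1 rose by 0.30 (log2) and Gpr17 and Lims2 fell (list alone, 2 rose and 3 fell). Gpr17 (chromosome 18, 31942997 to 31949636, minus strand) lies within Lims2 (31922290 to 31958619, plus strand). The kit does not mark strand, so reads of Gpr17 may count for Lims2 and its fall may not be a separate one. There the median was 0.09 and the mean -0.37, and the fry test pointed down (adjusted p = 0.0617).

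Sox10, a transcription factor of the whole lineage, was the 1 member of the 11 differentiation factors that changed, from 29.2 to 14.2 and 15.1 CPM (log2 -0.97, adjusted p = 0.00356); that list's median was -0.000615, and 0.00757 with library totals (fry adjusted p = 0.409). Of 13 progenitor or inhibitory factors Hey1 rose and Sox9, Id2 and Sox2 fell (list alone, 2 rose and 4 fell; median 0.04, mean -0.01, fry pointing down with adjusted p = 0.409). No gene of the 24 for cholesterol synthesis or the 17 for fatty acid and sphingolipid synthesis was called by edgeR (fry adjusted p = 0.647 and 0.339). Of 30 cell cycle genes, Aurka and Kif11 fell over all genes, and 17 fell when adjusted over the list alone (median -0.24). The fry test gave adjusted p = 0.0421, which became 0.274 by camera with an estimated correlation, 0.0585 with a length offset and 0.0512 with the length trend removed.

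Markers of other cell types moved in targeted OPCs as well. Of 15 measured astrocyte genes, Gja1 and Apoe rose (5 over the list alone; median log2 0.28). Of 15 neuron genes Nefl, Tubb3, Nefm and Ina fell and Stmn2 rose, at 0.089 CPM in controls and 1.15 and 1.06 CPM with the guides; over the list alone 7 fell and 1 rose. The neuron median was -0.25 and the mean 0.10, and the fry test pointed down. Each list had fry adjusted p = 0.0421 and camera adjusted p = 0.274 with an estimated correlation, and a length offset gave the neuron list 0.118. The OPCs had been sorted for CD140a and NG2, and 15 of the 17 astrocyte genes and 15 of the 18 neuron genes passed the count filter in these libraries. Which cells held this RNA was not tested.

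The control OPC libraries were uneven. The log2 ratio of a library to the others of its group had a Spearman rho with transcript length of -0.499 in control A and 0.528 in control C, against -0.219 to 0.151 in the targeted OPC libraries, and on the second principal component (17.86% of the variance) these controls lay at 22.28 and -51.74. The edgeR test called 479 of 13358 genes in targeted OPCs, 261 higher and 218 lower, of which 19 and 37 changed at least 2-fold. The count moved by over 1.5 times without control library B (185), guide 1 library A or B (149 and 154) or guide 2 library A, B or C (248, 274 and 277). It was 816 with DESeq2, 236 with a transcript length offset and 254 with both stages in 1 fit. The authors' deposited table called 611 genes, of which 387 were among the 479.

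The second SOX6 comparison asks the same of cells in differentiation medium. There, the myelin genes Mobp and Ermn were far higher after targeting, and Gpr17 and Bcas1, genes of newly formed oligodendrocytes, were lower. Mobp, which encodes a myelin protein, stood at 1.43 ± 0.413 CPM in controls, 65.4 ± 3.03 CPM with guide 1 and 73.0 ± 6.92 CPM with guide 2 (SD, n = 3 each), which is 48.4-fold higher (95% interval 37.8 to 62.1). Ermn, for the myelin cytoskeletal protein ermin, went from 0.242 ± 0.185 to 12.5 ± 1.13 and 10.4 ± 1.12 CPM. Gpr17 fell from 1641 ± 42.7 to 422.2 ± 100 and 595.1 ± 21.5 CPM, Bcas1 from 876.6 ± 14.9 to 372.6 ± 26.9 and 438.4 ± 15.7 CPM, and Neu4 from 78.2 ± 4.08 to 17.5 ± 1.58 and 23.1 ± 0.397 CPM. Mki67, a marker of dividing cells, fell from 130.5 ± 3.07 to 52.7 ± 17.8 and 55.1 ± 2.64 CPM.

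By edgeR the log2 changes were 5.60 for Mobp (SE 0.183, adjusted p = 3.71e-06), 5.54 for Ermn (SE 0.402, adjusted p = 0.000129), -1.71 for Gpr17 (adjusted p = 0.000173), -1.12 for Bcas1 (SE 0.0629, adjusted p = 2.65e-05) and -1.962 for Neu4 (SE 0.0795, adjusted p = 7.62e-06). Col9a1, a collagen IX chain, changed by 6.15 (SE 0.896), from 0.219 ± 0.262 to 18.8 ± 14.3 and 15.3 ± 9.22 CPM. The control levels of Ermn and Col9a1 lay near the value of 3 counts (0.179 to 0.222 CPM), so their fitted changes are imprecise. Other rises were in Pkd2l1 (2.92), Nkain2 (2.62), Galnt13 (2.37), Prr5l (2.24), Srrm4 (2.23), Cdh8 (2.14) and Ptpru (2.06). Other falls were in Rcan1 (-5.48), Capn6 (-2.40), Vgll2 (-2.33), Col11a2 (-2.33), Stk32a (-2.32), Prkg2 (-2.19), Elfn2 (-1.92), Dll3 (-1.91) and Lims2 (-1.86). Lims2 overlaps Gpr17 on the other strand, so its fall may not be separate from that of Gpr17. The adjusted p of the 20 named genes ran from 3.71e-06 to 0.0238, and 17 kept their call in every alternative. Rcan1, at 29.6 ± 27.6 CPM in controls, lost it without control library A or C or guide 2 library B or C (adjusted p = 0.0841, 0.159, 0.0582 and 0.0641) and with DESeq2 (0.0647). Col11a2 and Prr5l lost it with a length offset (0.0538 and 0.133).

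Of 18 measured myelin genes, 6 rose and 2 fell (9 and 4 over the list alone), with a median log2 change of 0.44. The abundant Mbp rose modestly, from 704.9 ± 48.4 to 870.4 ± 45.5 and 997.4 ± 22.3 CPM. Cldn11 (log2 1.13) and Apod (1.53) rose as well, and Fa2h (-0.87) and Gsn (-0.42) fell. Of 15 newly formed oligodendrocyte genes, Frmd4a rose and 6 fell (list alone, 2 and 7), with a median of -0.50. Of 21 progenitor genes Ednrb rose and 8 fell (list alone, 1 and 10), with a median of -0.36. Among those that fell were Cspg4 (185 to 97.8 and 121.6 CPM) and C1ql1 (91.7 to 25.8 and 29.1 CPM). Of these, C1ql1 stood higher in control OLs than in control OPCs (14.3 CPM), and Cspg4 stood lower. Adjusted p for these lists was 0.000355, 7.18e-06 and 0.00012 by fry, and 0.0259, 0.00279 and 0.00517 by camera with an estimated correlation.

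Sox10 fell from 265.6 ± 9.39 to 132.2 ± 7.52 and 161.6 ± 3.78 CPM, and of the 12 differentiation factors Nkx2-2 and Olig2 fell too (list alone, 4 fell; median -0.21; fry adjusted p = 0.00432, camera adjusted p = 0.131 with an estimated correlation). Of 13 progenitor or inhibitory factors the Notch pathway genes Hes5 and Hey1 rose (list alone, 4 rose and 3 fell; fry adjusted p = 0.181). That list's median was 0.06, and -0.006 with library totals. With the length trend removed or without the libraries that stood apart, its fry adjusted p was 0.0131 or 0.0119.

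Of 24 cholesterol synthesis genes 6 rose and none fell in targeted OLs (11 rose over the list alone), with a median of 0.39; Hmgcs1, an early enzyme of the pathway, went from 2138 to 3285 ± 486 and 2862 ± 179 CPM. The fry test gave adjusted p = 2.43e-07, and camera with an estimated correlation 0.0066. Of 17 fatty acid and sphingolipid genes Scd1, Scd2, Fads1 and Fads2 rose (list alone, 5), with a median of 0.09, and 0.0172 with library totals (fry adjusted p = 0.0157, camera adjusted p = 0.256 with an estimated correlation). Of 15 unfolded protein and integrated stress genes 4 rose (list alone, 7), among them Chac1 (8.78 to 19 and 19.2 CPM) and Slc7a11 (69.8 to 126 and 167.1 CPM), with a median of 0.45 (fry adjusted p = 0.00149, camera adjusted p = 0.0624 with an estimated correlation). Of 27 cell cycle genes 16 fell and none rose (list alone, 20), with a median of -0.85 (fry adjusted p = 2.44e-05, camera adjusted p = 0.00517 with an estimated correlation).

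Beside these groups, astrocyte markers stood higher in targeted OLs, at 8395 ± 595 and 8615 ± 128 CPM in sum against 7095 ± 197 CPM in controls. Of 15 measured ones, Cd44 and Aldoc rose (also 2 over the list alone; median 0.21; fry adjusted p = 0.00871, camera adjusted p = 0.126 with an estimated correlation). Of 14 neuron genes Nefl, Nefm and Rbfox3 fell (list alone, 4); the median was -0.06 and the mean 0.03, and the fry test pointed down (adjusted p = 0.00522, camera adjusted p = 0.279 with an estimated correlation and 0.0962 by fry with a length offset). Of these lists, 15 of 17 astrocyte genes and 14 of 18 neuron genes passed the count filter; the culture was not sorted, and which of its cells held this RNA was not tested. Library B of guide 1 OLs stood apart, at -99.9 on a first principal component with 31.2% of the variance, where the other OL libraries lay between 6.77 and 20.8. It had 6.79% mitochondrial and 4.07% ribosomal protein counts. Library B of guide 2 OLs lay at -60.0 on the second component (18.3%).

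The edgeR test called 874 of 13447 genes in targeted OLs, 421 higher and 453 lower, of which 96 and 165 changed at least 2-fold. Higher genes made up 48.2% of calls with TMM and 36.3% with library totals (315 higher and 553 lower). Without control library A, B or C the count was 371, 353 or 407, without guide 2 library A or C it was 513 or 546, and without guide 1 library B it was 2337, which kept 873 of the 874. Without both libraries that stood apart it was 2638, with all 874 kept; DESeq2 called 1500, both stages in 1 fit 1604, a length offset 582 and removal of the length trend 1602. The authors' deposited table called 995, of which 711 were among the 874.

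**Figure D3:**
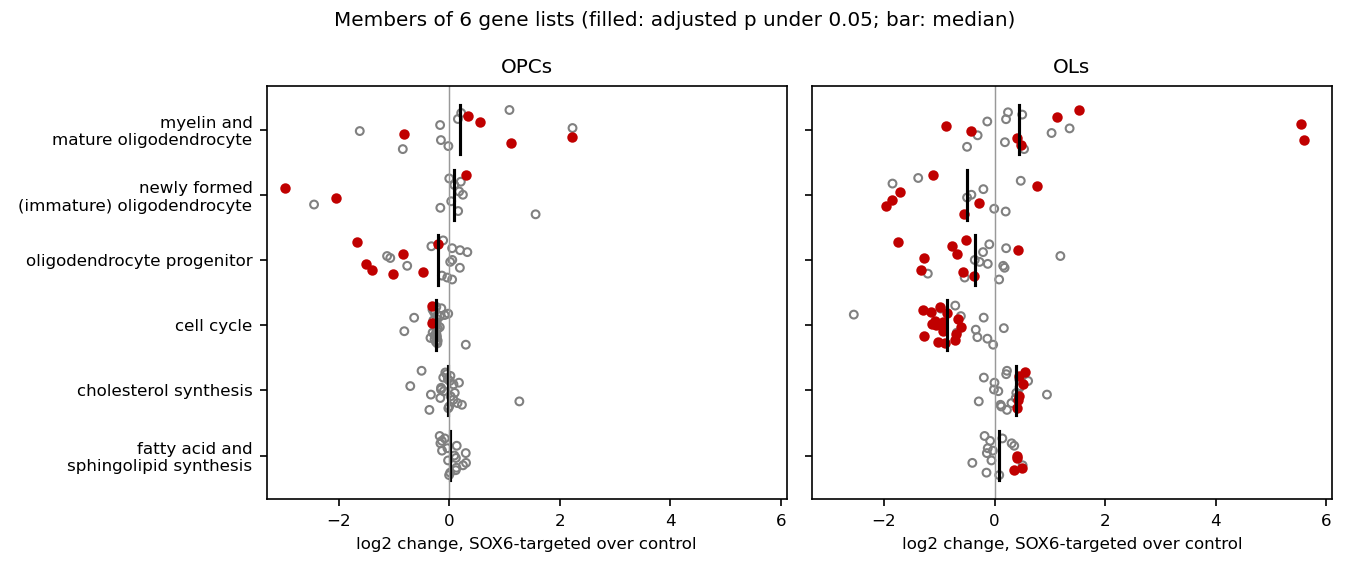
Log2 change of each measured member of 6 gene lists in SOX6-targeted OPCs and OLs, mean of both guides; filled red points passed the test (adjusted p under 0.05) and bars mark medians. In OLs the medians were 0.44 for myelin genes, -0.50 for newly formed oligodendrocyte genes, 0.39 for cholesterol synthesis and -0.85 for cell cycle.

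Both guides gave calls in common. In OPCs guide 1 changed 372 genes (176 higher and 196 lower) and guide 2 changed 273 (177 and 96), with 108 higher and 66 lower in both and 0 called in opposite directions. In OLs guide 1 changed 661 (321 and 340) and guide 2 changed 597 (310 and 287), with 219 higher and 214 lower in both. Independent lists of those sizes would share 2.33 and 1.41 genes in OPCs and 7.4 and 7.26 in OLs. In 20 draws per stage with all libraries simulated from equal means, controls included, the guides shared 0 genes. The draws hold no trend that runs through a whole library, such as that of the real control OPCs with transcript length. They cannot judge agreement that arises from such a trend. Across genes the Pearson r between guides was 0.51 in OPCs, against a simulated mean of 0.435, and 0.621 in OLs, against 0.509. The covariance exceeded the simulated one by 0.117 (0.2 against 0.083) in OPCs and by 0.139 (0.249 against 0.111) in OLs. The 3 controls of a stage could not be divided into parts of at least 2, so part of the excess may come from the shared controls. The 174 calls shared in OPCs became 77 without control B, 7 and 17 without guide 1 library A or B, and 72, 71 and 74 without guide 2 library A, B or C. The 433 shared in OLs became 170, 172 and 171 without control A, B or C, 1368 without guide 1 library B, and 216, 275 and 227 without guide 2 library A, B or C.

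In the direct contrast of guide 2 with guide 1, edgeR called 0 genes in either stage. In OPCs 1106 genes had an unadjusted p under 0.05 and DESeq2 called 112; in OLs these were 773 and 29. A single library changed the count to 26 in OPCs without control library A and 1 without guide 1 library B, and to 1 in OLs without guide 1 library A. Of 30 cell cycle genes in OPCs, 13 were called lower with guide 1 (19 over the list alone, median -0.42; fry adjusted p = 0.0285, camera adjusted p = 0.157 with an estimated correlation) and 0 with guide 2 (median -0.06, fry adjusted p = 0.466). In the direct contrast of the guides this list did not pass fry (adjusted p = 0.108) or camera with an estimated correlation (adjusted p = 0.178). It passed camera with the preset correlation of 0.01 (adjusted p = 1.51e-29), far below the estimated 0.33. The contrast called 0 of its genes over all genes, with a median of 0.39 and 19 genes higher over the list alone. In OLs, 0 of 15 newly formed oligodendrocyte genes and 0 of 24 cholesterol synthesis genes were called between the guides (list alone, 1 higher with guide 2 and 1 lower). The first list pointed up with guide 2 (median 0.143, fry adjusted p = 0.0322, camera adjusted p = 0.177 with an estimated correlation) and the second down (median -0.157, fry adjusted p = 5.34e-05, camera adjusted p = 0.165 with an estimated correlation).

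Counts per guide depended on single libraries. In OPCs the guide 1 count was 177 without control B, 614 without control C, 7 and 20 without its own library A or B, and 226 and 238 without guide 2 library A or B; that of guide 2 was 94 without control B, 132 without either guide 1 library, and 78, 80 and 89 without its own A, B or C. In OLs the guide 1 count was 275, 263 and 256 without control A, B or C, 1580 without its own library B, and 409 and 434 without guide 2 library A or C. That of guide 2 was 218, 212 and 231 without control A, B or C, 2147 without guide 1 library B, and 240, 313 and 266 without its own A, B or C. With library totals the share of higher calls in OLs went from 48.6% to 38.4% for guide 1 and from 51.9% to 40.4% for guide 2.

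The last comparison asks whether OLs and OPCs responded alike. Of 12829 genes tested in both stages, 116 rose in both and 98 fell in both, and 6 were called in opposite directions. Independent lists, with every gene equally likely to be called, would share 8.16 and 7.32. The control libraries were separate, but whether both stages came from the same transduced cells was not known here. A shared difference unrelated to SOX6 is therefore not excluded. Pearson's r across genes was 0.207 and Spearman's rho 0.254. Gpr17, C1ql1, Dll3, Lims2, Sox10 and Lhfpl3 fell in both, and Mbp rose in both. The fall of Lims2 may reflect reads of Gpr17, which it overlaps. The difference between the responses was tested directly. Bcas1 rose by 0.30 in OPCs and changed by -1.12 in OLs, a difference of -1.39 (SE 0.0806, adjusted p = 9.58e-07). Gpr17 fell less in OLs, by a difference of 1.28 (SE 0.219, adjusted p = 0.00783). Mbp rose more in OPCs, from a much lower level (difference -1.79, SE 0.244, adjusted p = 0.00154), and Mki67 fell in OLs (-1.28) but had no call in OPCs (-0.235, adjusted p = 0.201), a difference of -1.02 (SE 0.217, adjusted p = 0.0281).

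In all, 243 of 14352 genes differed in response by edgeR, 132 higher and 111 lower in OLs than in OPCs, with 39 and 29 differing at least 2-fold. With library totals the split was 86 and 161, so the share of higher calls went from 54.3% to 34.8%, and the median of all genes moved by -0.101. The count was 140, 133 and 153 without OPC control A, B or C, 114 and 132 without OPC guide 1 library A or B, 113, 116 and 122 without OL control A, B or C, and 638 without OL guide 1 library B. Of 24 cholesterol synthesis genes 3 differed upward (14 over the list alone, median 0.44; fry adjusted p = 0.000463, camera adjusted p = 0.00728 with an estimated correlation). Of 30 cell cycle genes 9 differed downward (15 over the list alone, median -0.59; fry adjusted p = 0.000463, camera adjusted p = 0.00728 with an estimated correlation). Of 15 unfolded protein and integrated stress genes 4 differed upward (9 over the list alone, median 0.54; fry adjusted p = 0.000867, camera adjusted p = 0.0216 with an estimated correlation). Stage and table cannot be told apart here either, although each response was measured against controls of its own table.

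**Figure D4:**
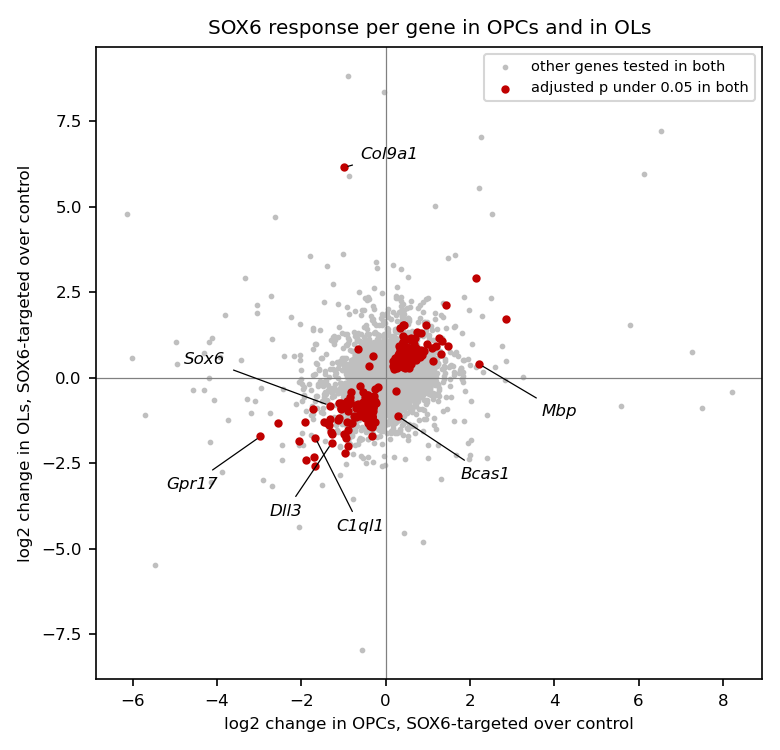
Log2 change after SOX6 targeting in OPCs (x axis) and in OLs (y axis), mean of both guides, 1 point per gene tested in both stages; red points passed the test (adjusted p under 0.05) in both. Across the 12829 genes r was 0.207; Gpr17, C1ql1 and Dll3 lie at the lower left, and Col9a1 and Bcas1 have opposite signs in the stages.

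Genes that set sorted OLs apart did not move as 1 group. Of 608 tested genes at least 4-fold higher in sorted OLs, 46 rose and 121 fell in targeted OLs (75 and 165 over the list alone), with a median of -0.205 (fry adjusted p = 6.3e-06, camera adjusted p = 0.00048 with an estimated correlation). Of 565 genes at least 4-fold higher in sorted OPCs, 44 rose and 92 fell (72 and 140 over the list alone), with a median of -0.161 (fry adjusted p = 2.17e-05, camera adjusted p = 0.00469 with an estimated correlation). With genes at least 2-fold higher in sorted OLs or OPCs the medians were -0.0504 (78 rose and 173 fell; fry adjusted p = 7.9e-05, camera adjusted p = 0.00229 with an estimated correlation) and -0.0285 (122 rose and 130 fell; fry adjusted p = 0.00462, camera adjusted p = 0.361 with an estimated correlation). In targeted OPCs, 30 rose and 33 fell of 550 OL genes (list alone, 42 and 49; fry adjusted p = 0.562), and 30 rose and 49 fell of 581 OPC genes (list alone, 53 and 143; median -0.143; fry adjusted p = 0.0418, camera adjusted p = 0.221 with an estimated correlation). By guide, 20 of those OPC genes were called higher and 86 lower with guide 1 (median -0.201, fry adjusted p = 0.00784, camera adjusted p = 0.0508 with an estimated correlation) and 25 were called higher and 8 lower with guide 2 (median -0.0427, fry adjusted p = 0.947). Across genes, the change after targeting in OLs had r = -0.0293 with that from sorted OPCs to sorted OLs, and the change in OPCs had r = 0.022.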

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

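The tests of transcript length bias, of RNA from another cell type and of the spread left after the length trend in library B, and that of a larger share of differentiated cells, were chosen only after the result was seen.

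The response to SOX6 targeting differed between OLs and OPCs by the direct test in 243 genes. The largest differences upward in OLs, as log2, were in Col9a1 (7.16, with -0.99 in OPCs and 6.15 in OLs), Nkain2 (2.92), Galnt13 (2.80), Chrm3 (2.54) and Prr5l (1.66). The largest downward were in Mbp (-1.79), Rab7b (-1.75), Dixdc1 (-1.63), Epha3 (-1.62) and Lima1 (-1.42). Col9a1 stood at 0.219 ± 0.262 CPM in control OLs (SD, n = 3), near the value of 3 counts, and its difference had an SE of 0.866. In control OPCs Galnt13, Mbp and Rab7b stood at 0.91, 0.558 and 0.472 CPM, and in control OLs Chrm3 stood at 0.937 CPM. Differences that rest on such low levels are imprecise, and so is their ranking. Lima1 stood at 76.3 ± 4.22 CPM in control OPCs and 244.8 ± 8.93 CPM in control OLs, and at 75.4 ± 8.64 and 94.4 ± 5.01 CPM in OLs with guide 1 and guide 2 (SD, n = 3 each). The call of Rab7b was lost without OPC control A or C (adjusted p = 0.0799 and 0.0633), OPC guide 1 library A (0.0769) or OL control A, B or C (0.0587, 0.0698 and 0.071) and with no count filter (0.0557). Calls of Dixdc1, Epha3 and Prr5l were lost with a transcript length offset (0.108, 0.0971 and 0.516). Lists differed between stages too, with fry adjusted p = 0.000463 for cholesterol synthesis, 0.000463 for cell cycle, 0.000867 for unfolded protein and integrated stress genes, and 0.00135 for the genes at least 4-fold higher in sorted OLs. The fatty acid and sphingolipid list (fry adjusted p = 0.0557) gained a call with the length trend removed (0.00114) and without both OL libraries that stood apart (0.00158). With a length offset it did not (0.0678). Progenitor or inhibitory factors (0.139) gained a call without those libraries (0.0185) but not under either length setting (0.0678 and 0.0682).

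Library B of guide 1 OLs stood apart from the other OL libraries. No marker list of another cell type stood far above the other OL libraries. The largest ratio to the highest other OL library was 1.04, for astrocytes (9075 against 8762 CPM). Their most abundant gene, Apoe, stood at 3948 against 2963 CPM. Long transcripts read low in library B, which can lower such sums, and cell types without a list were not examined. RNA from another cell type is thus not excluded. A control library under a wrong label is argued against. Library B lay closer to the guide 2 mean than to the control mean at 79.2% of 597 genes called with guide 2. Libraries A and C of guide 1 OLs did so at 94.6% and 93.6%. The log2 ratio of library B to the others of its group fell with transcript length across genes (rho -0.674). In OL libraries of the other groups rho was -0.196 to 0.28, so a length bias may be part of the cause. After removing the trend the SD over genes was 0.623, above the 0.214 to 0.366 of OL libraries of the other groups. A trend on this length as the whole cause is therefore argued against. The length was that of the longest annotated transcript of each gene, so a bias acting on the transcripts present was not excluded as the whole cause. No biological explanation was tested.

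By fry, the myelin list rose and the list of newly formed oligodendrocyte genes fell in targeted OLs, although of 18 myelin genes 6 rose and 2 fell. A larger share of cells like the sorted OLs would raise the genes high in them together, but their median change was -0.205 (fry adjusted p = 6.3e-06). With the genes at least 2-fold higher it was smaller, at -0.0504, and still down (fry adjusted p = 7.9e-05). These sets hold genes of newly formed oligodendrocytes, such as Gpr17 and Bcas1, and so part of the fall to be explained. They therefore cannot decide whether the differentiated cells stood at a later stage, which was not tested. A length bias between libraries that these settings capture is argued against. The larger fry adjusted p of both lists was 0.00146 with a length offset or without the libraries that stood apart. It was 1.18e-05 with the length trend removed, and directions were kept. That trend was on the longest annotated transcript, so a bias acting on the transcripts present was not excluded. An effect of SOX6 targeting on genes of both lists may be the cause and stays a hypothesis: no test here decides it, it was found in these data, and the labels name no separate cultures.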

How the results depend on the processing

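The transcript length offset, the removal of the length trend, the omission of both OL libraries that stood apart and the count of calls shared by the guides under alternatives were chosen only after the data were seen. No gene taken by the rule for named genes changed its direction, and no list called by fry over both guides or for the stage difference did so under camera, the length settings or the omission of both libraries; lists of single guides, between guides and between control stages were not run under the length settings or that omission. Medians near 0 did: with library totals those of the differentiation factors in targeted OPCs (-0.000615 to 0.00757) and, in targeted OLs, of the progenitor or inhibitory factors (0.0614 to -0.006) and the p53 list (0.057 to -0.00984). By guide they also did for differentiation factors with guide 1 in OPCs (-0.0033 to 0.0119), for p53 (0.017 to -0.0589) and interferon (0.0297 to -0.0435) with guide 1 in OLs, and for fatty acid and sphingolipid (0.0142 to -0.0458) and neuron genes (0.0323 to -0.0282) with guide 2 in OLs; of these, fry called the p53 list (adjusted p = 0.0106, pointing down) and the fatty acid list (0.02, up). The median of long genes in targeted OLs went from -0.0273 to 0.0278 with the length trend removed and to 0.0262 without the libraries that stood apart. Lists without a call also turned, such as the myelin list in the stage difference (fry adjusted p = 0.995, pointing up) with the length trend removed (0.856, down) and the pluripotent list in targeted OLs (0.515, up) without those libraries (0.928, down). The counts between control OLs and control OPCs and between sorted OLs and sorted OPCs stayed within 1.5 times in every alternative. Of the named genes, 20 of 20 in the sorted cells, 17 of 20 in targeted OLs, 12 of 19 in targeted OPCs and 6 of 10 of the stage difference kept their call in every alternative. In the counts below the cause of a change was not tested, except that leaving out a library leaves fewer samples. No paired analysis was possible because the columns of the count tables carry letters and not the replicate numbers of the labels; a fit blocked on the letters was not run, since no source says that they pair libraries.

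Leaving out 1 library at a time gave 149 to 550 genes in targeted OPCs, 7 to 614 with guide 1 and 78 to 254 with guide 2. It gave 353 to 2337 in targeted OLs, 256 to 1580 with guide 1 and 212 to 2147 with guide 2. Between guides it gave 0 to 26 in OPCs and 0 to 1 in OLs, and for the stage difference 113 to 638. Calls shared by both guides, 174 in OPCs and 433 in OLs, ran from 7 to 200 and from 170 to 1368. Where 1 library was left of guide 1 OPCs, it was assumed to vary like the other groups. Sox6 in targeted OLs ran from -0.88 to -0.72 (log2).

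DESeq2 called 816, 801 and 518 genes in OPCs (both guides, guide 1, guide 2) and 1500, 1281 and 1137 in OLs. It called 112 and 29 between guides in OPCs and OLs and 525 for the stage difference, with 345 and 798 calls shared by the guides. In simulation 40 of 180 DESeq2 calls in OPCs and 44 of 164 in OLs were false, against 5 of 132 and 8 of 107 with edgeR. Those counts were drawn with the spread that edgeR had estimated, so they cannot decide which test was nearer the truth in the real libraries. The transcript length offset gave 236, 167 and 110 in OPCs, 582, 431 and 328 in OLs, 104 for the stage difference and 72 and 252 shared calls, and changed Sox6 in OLs to -0.86 (adjusted p = 0.105). Removing the length trend gave 590 with guide 1 in OPCs, 1602, 1245 and 1239 in OLs, 500 for the stage difference, and 277 and 913 shared calls. Without both libraries that stood apart, OLs gave 2638, 1930 and 2179, the stage difference 674, and the guides shared 1519 calls. With both stages in 1 fit, OPCs gave 254 and OLs 1604. With no filter beyond 1 count, 31 genes differed between guides in OPCs. For genes high in sorted OPCs, adjusted p in targeted OPCs was 0.221 by camera with an estimated correlation, against 0.0418; for the stage difference it was 0.0169 by camera with the preset correlation and 0.0392 with the length trend removed, against 0.097. With the 2-fold cut the fry calls for genes high in sorted cells stayed the same, while the medians in targeted OLs shrank from -0.205 to -0.0504 and from -0.161 to -0.0285.

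At these depths 2-fold changes were recovered in simulation for 64.2% of OPC and 55.2% of OL genes, so genes without a call cannot be taken as unchanged.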

Other observations

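The test of long genes and the splits of the libraries were planned before their results were seen; the list levels below were read off after.

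Cartilage genes, several of which are known to depend on SOX proteins, moved in opposite directions in OLs. Of 7 measured, Matn1 fell from 8.93 to 0.987 and 1.08 CPM with guide 1 and guide 2, Acan from 5.10 to 1.24 and 1.27 CPM, and Col11a2 from 18.9 ± 3.17 to 3.47 ± 2.41 and 4.02 ± 0.355 CPM, while Col9a1 rose (over the list alone, 1 rose and 4 fell). The list's median was -0.95 and its mean -0.27 (fry adjusted p = 0.000342, camera adjusted p = 0.0259 with an estimated correlation). In OPCs, of 5 measured, Col9a1 fell from 6.63 ± 0.527 to 2.38 ± 0.0392 and 4.55 ± 1.1 CPM (fry adjusted p = 0.104). All 5 measured cartilage genes rose from sorted OPCs to sorted OLs, where the list summed to 4.84 ± 0.396 and 168.6 ± 20.5 TPM. Slow muscle genes, of which 4 were measured in OPCs and 2 in OLs, had no call (fry adjusted p = 0.647 and 0.325).

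Of 18 p53 response genes, Cdkn1a fell in targeted OPCs (list alone, 1 rose and 3 fell), with a median of -0.13. There the fry adjusted p was 0.0421, and the call was lost with a length offset (0.118) and with the length trend removed (0.0533). Camera with an estimated correlation gave adjusted p = 0.292. Btg2 and Trp53inp1 fell in targeted OLs (list alone, 3), with fry adjusted p = 0.0132 pointing down and camera adjusted p = 0.341 with an estimated correlation. In OLs that list had a median of 0.06, a mean of -0.07 and a median of -0.01 with library totals. Of 13 unfolded protein and integrated stress genes in OPCs, Slc7a11 rose (fry adjusted p = 0.578). Of 11 interferon response genes in OPCs none was called over all genes (list alone, 1 rose; median -0.14, mean 0.16, fry pointing down with adjusted p = 0.647), and of 10 in OLs Rsad2 fell by 1.58 on the log2 scale (median 0.11, mean -0.001, fry pointing down with adjusted p = 0.158). Fibroblast or pericyte genes (8 measured in OPCs, 7 in OLs), Schwann cell genes (3 and 4) and pluripotent cell genes (3 and 3) had no call over all genes, with fry adjusted p of 0.623 and 0.138, 0.339 and 0.0967, and 0.409 and 0.515; a length offset gave the fibroblast list 0.0158 in OLs. No microglia gene passed the filter in OPCs; 2 did in OLs (fry adjusted p = 0.244), and the list summed to 1.36 ± 0.477 CPM in control OPCs and 2.05 ± 0.476 CPM in control OLs.

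Sox6 spans 567925 bp, and the hypothesis was tested that genes spanning at least 100 kb fall together in targeted OLs. The 1951 such genes had a median log2 change of 0.0458 with guide 2, above the range of -0.0215 to 0.00379 that holds the central 95% of 10000 random lists matched on expression, and of -0.0903 with guide 1, below its range of -0.000866 to 0.0319. Over both guides it was -0.0273, and 0.0262 without the libraries that stood apart, so the sign depended on those libraries and a common fall was not seen. From control OPCs to control OLs, 2060 such genes had a median of 0.178 (range of random lists -0.0267 to 0.0432).

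Other splits of the libraries tested whether chance could give such counts. In targeted OPCs 1 of 100 splits, the real one, gave as many as 479 genes, and the highest other gave 251; in targeted OLs it was 1 of 100, with 874 genes and 42 in the highest other. For the stage difference 3 of 80 splits gave 243 genes or more. The other two were 297, with 1 OPC control and 3 OL controls in the control group, and 924, with 0 OPC controls and 3 OL controls, which turns the OPC response round and so follows the structure of the groups. In targeted OPCs and in targeted OLs the share lay under 0.05, which argues against chance among these libraries, which may not be separate cultures. For the stage difference both stages were split at once, and all 3 of these splits kept the 3 OL controls. Those splits test for no effect in either stage and cannot decide whether the responses differ. In designs of 3 against 3 libraries the 10 splits are too few for a share under 0.05. There, 1 of 10 splits gave as many for guide 2 in OPCs (273, highest other 1), guide 1 in OLs (661, highest other 0), guide 2 in OLs (597, highest other 0), control OLs against control OPCs (6178, highest other 0) and the sorted cells (7160, highest other 1), and 10 of 10 for the guides against each other in OLs (0, highest other 1).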
